A study of Drosophila melanogaster with 2 samples.

How the data were processed

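HmgZ-eGFP ChIP-seq peak lists from 2 biological replicates of embryos aged 4 to 24 h were analysed, with chromatin sheared by sonication to 200 to 800 bp per the labels. Per the files' accompanying descriptions, regions were called in each replicate and in the pooled reads against 1 shared control alignment, on dm6, and the thresholded set was derived from those 3 lists. The aligner and the peak caller are not given in the sources used here. Each region has a deposited signal value, whose scale differs between lists, and a deposited -log10 q-value, which stops at a maximum of 4.23 in the pooled list (reached by 8539 of 30000 regions) and was therefore not used to rank peaks. Read depth is unknown, and intervals printed with shares cover counting error only. Signal values are the authors', and were used to describe and rank peaks within a list.

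Regions were ranked by signal and represented by their summits. For comparison between replicates, the signal of the region with a summit within 100 bp was divided by the median of that replicate's list, or turned into a percentile. The arms 2L, 2R, 3L, 3R, 4 and X were analysed, and other sequences were not analysed here. The genome sequence was the RefSeq copy of the same assembly as dm6, with the Ensembl 115 gene annotation. Annotated transposable elements and pseudogenes were left out of gene features and TSSs, a choice made after the lists were seen and before any result was computed. Each base was given the first class that applied among promoter (within 250 bp of a TSS), 5' UTR, coding exon, 3' UTR, exon of a non-coding gene, intron and intergenic.

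Shares and distances were compared with 1000 random placements on the same arm outside undetermined bases, with two-sided empirical p-values, and replicate overlap with a one-sided one. Arm counts were tested with exact binomial tests, gene lists and motifs with two-sided Fisher's exact tests, base composition with paired sign-flip tests and signal with permutation tests, both with 100000 resamples. Benjamini-Hochberg adjustment was applied within each family, with a threshold of 0.05. Log2 odds ratios had 0.5 added to each cell. A gene was called bound if a summit lay within 250 bp of one of its TSSs, and lists were compared with all other protein-coding genes. Motifs were matched as consensus sequences on both strands within 100 bp of the summit. Control windows, 5 per peak, were on the same arm, matched in G+C count within 2 bases and over 500 bp from any peak. Differences between promoter and other peaks in log2 odds ratio were tested with a normal approximation.

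The tests, the 30 gene lists, the 24 motifs, the alternatives listed as planned and the rule for named genes were fixed before the data were examined. The rule took HmgZ, HmgD and Dsp1, the 12 peaks of highest mean percentile, up to 3 bound members of each called list by mean percentile, and the 3 windows of 50 kb with most peaks. Genes named in the dense windows and the motifs printed were chosen after their values were seen. Alternatives were stricter peak sets, single replicates, other windows, other backgrounds and other summaries. Those added after seeing the data were placement on unique 32-mers, shifting all peaks of an arm together, peaks matched in both replicates, genes with 90% or more unique 32-mers near their TSSs, the split of motifs by peak class and the chorion list without Cp110 and Cp190.

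The functions were tested on simulated data. With 6844 random peaks, 0 of 7 feature classes, 0 of 6 arms and 0 of 24 motifs were called. With peaks planted at TSSs, a promoter share of 44.4% was planted and 44.2% was found. Over 20 draws of bound genes, 3 of 520 list tests with nothing planted were called and 20 of 20 planted lists were recovered. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.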

Results

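Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos of both sexes, aged 4 to 24 h, from a transgenic line that carries HmgZ fused to green fluorescent protein at its C-terminus. HmgZ is a small chromatin protein with a high mobility group (HMG) box, a DNA-binding fold. There was 1 group with 2 biological replicates, numbered 1 and 3, and no second condition, so the comparisons are between replicates, between peaks and random positions, and between groups of genes. The free-text description of both samples calls them input controls, whereas the antibody, the assay name and the peak lists describe an HmgZ ChIP, and they are treated here as ChIP samples. An age field holds a number of hours that no embryo reaches, and the 4 to 24 h of the sample source is used instead. The lists hold no read counts, so the depth of each replicate is unknown. All coordinates are on dm6.

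The deposited set held 6844 peaks passing the irreproducible discovery rate (IDR) threshold, with a median width of 404 bp and a greatest width of 1036 bp, in 6642 separate intervals once overlapping peaks were merged. They were the 6844 regions of highest signal in the pooled list of 30000 regions, with the same values. Each replicate also had a list of 30000 regions. Among the 6844 strongest regions of replicate 1, 4711 (68.8%, 95% Wilson interval 67.7 to 69.9) had a summit of replicate 3's 6844 strongest within 100 bp, against 1.02% ± 0.124 (SD, 1000 placements) for randomly placed summits (one-sided p = 0.001, n = 6844, the smallest the placements can give). A region of the full list lay within 100 bp of 97.0% of the thresholded peaks in replicate 1 and of 97.1% in replicate 3. Across the 6443 peaks found in both, signal divided by the list median had a Spearman rho of 0.574 and, on a log2 scale, a Pearson r of 0.664. This correlation is across peaks, which are not independent replicates, and both lists were called against 1 shared control alignment. No ChIP from untagged embryos was analysed here.

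Peak summits lay mostly at gene starts. Of the 6844 summits, 4004 (58.5%, 95% Wilson interval 57.3 to 59.7) were within 250 bp of an annotated transcription start site (TSS), 7.86 times the 7.44% ± 0.321 (SD) of random positions on the same arms. Coding exons held 22 summits, 0.321% against 15.6% of random positions, and 3' UTRs held 1.15% against 4.72%. Introns held 27.2% against 41.2%, and intergenic sequence held 10.5% against 28.7%. Each of these 5 classes had an adjusted placement p of 0.0028, after Benjamini-Hochberg adjustment over 7 classes. It follows from the smallest two-sided p the 1000 placements can give (0.002). Every summit counts in a single class, so the high promoter share by itself lowers the others. The intron and intergenic results are therefore not independent of it. Summits outside promoters were not tested alone, so these values do not show that introns were avoided. The shares of the summits (n = 6844) in 5' UTRs (1.14% against 1.32%, adjusted p = 0.224) and in exons of non-coding genes (1.15% against 1.07%, adjusted p = 0.531) did not pass the test. The 5' UTR share passed as lower in the strongest 3422 peaks (adjusted p = 0.0280, n = 3422), and over all peaks (n = 6844) with promoters drawn to 1000 bp (0.00233), against the weakest pooled regions (0.00159) and on unique 32-mers (0.00699). The promoter fold was 4.37 against the weakest pooled regions, and 4.86 and 3.16 with promoters drawn to 500 and 1000 bp. Along the pooled list the promoter share fell from 62.7% in ranks 1 to 3000 to 12.7% in ranks 27001 to 30000.

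**Figure D1:**
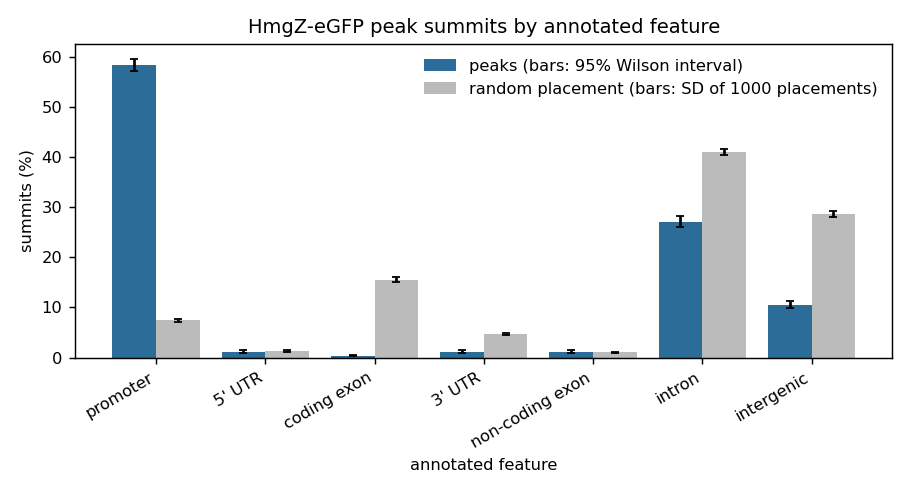
Share of HmgZ-eGFP peak summits (blue, percent of 6844, with 95% Wilson intervals) and of random positions (grey, mean with SD of 1000 placements) in each annotated feature. Promoters held 58.5% of summits and 7.44% of random positions, and coding exons held 0.321% and 15.6%.

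Summits sat upstream of the TSS more often than downstream. Within 1000 bp of a protein-coding TSS lay 4860 of the 6844 summits, at a median of -53 bp (quartiles -131 and 5 bp, negative values upstream). Random positions had a median of 109 bp ± 20.7 (SD; two-sided placement p = 0.002, n = 4860, the smallest possible). Of the summits within that distance, 73.4% were upstream, against 42.6% of random positions. The bin from 50 to 1 bp upstream held 15.6% of all summits.

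**Figure D2:**
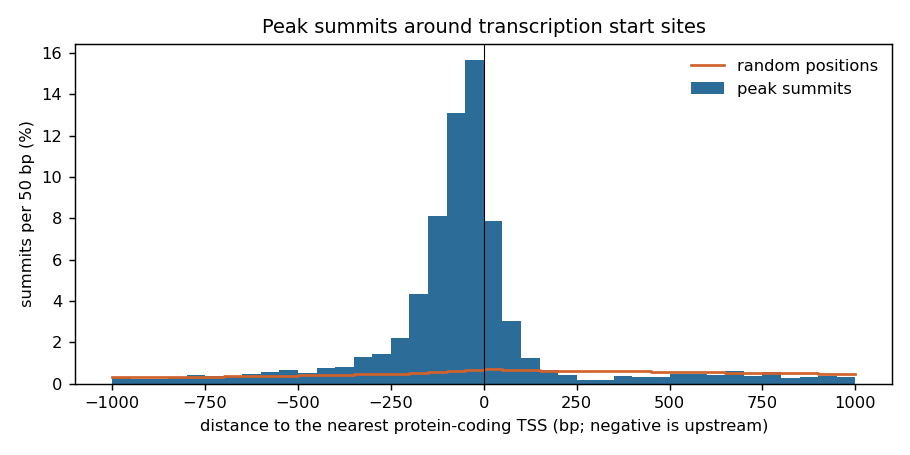
Percent of peak summits (blue bars) and of random positions drawn in proportion to the peaks per arm (orange line) in 50 bp bins of signed distance to the nearest protein-coding TSS, where negative values are upstream. The fullest bin, just upstream of the TSS, held 15.6% of summits and 0.688% of random positions.

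The strongest peaks by mean percentile in the replicates lay at 12 positions, 6 in promoters and 6 in introns. Signal is given as a multiple of the median of each replicate's list (mean ± SD, n = 2). On this scale replicate 3 was higher than replicate 1 by a median ratio of 1.18 over the peaks found in both and 1.31 over the top 500, and all 12 of these peaks were higher in replicate 3, so each SD includes that offset. The peak in an intron of CG11050 (2L 6612458 to 6612936) reached 53.9 ± 6.01 and the peak in the CG14100 promoter (3L 19590419 to 19590813) reached 54.8 ± 21.5. An intronic peak nearest cbt, a zinc finger gene, on 2L (480866 to 481339) reached 46.8 ± 8.64. Promoter peaks at Ugalt (X 2703692 to 2704088), mRpL41 (2R 15217584 to 15217938) and Art3 (3R 15229341 to 15229715) reached 43.3 ± 9.88, 39.1 ± 16.4 and 33.7 ± 8.43. The others were nearest Lk6, CenG1A, ph-p, CG1888 and CG9663, at 31.5 to 32.8, and HmgZ.

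The gene for the tagged protein was itself among them. HmgZ (2R 21697488 to 21707861) and its relative HmgD (2R 21701458 to 21716727) overlap, and the third-ranked peak, at 2R 21702660 to 21703695, lay in introns there, at -564 bp from the nearest HmgZ TSS. It was the widest of the thresholded peaks (1036 bp) and had a signal of 34.6 times the median in replicate 1 and 70.6 times in replicate 3. Further peaks at 2R 21705803 to 21706324 and 21704375 to 21704986 reached 20.3 ± 2.15 and 18.5 ± 0.609. Because the genes overlap, a peak there cannot be given to either alone. Around Dsp1, another HMG-box gene (X 16333612 to 16340624), 3 peaks were found. The strongest (X 16332841 to 16333168, 10.9 ± 3.88) lay before the gene's start and nearest a TSS of CG9921, and the peak in the Dsp1 promoter (X 16333479 to 16333882) reached 3.63 ± 1.13. No test compares single peaks, and 2 replicates limit the precision of each SD.

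**Figure D3:**
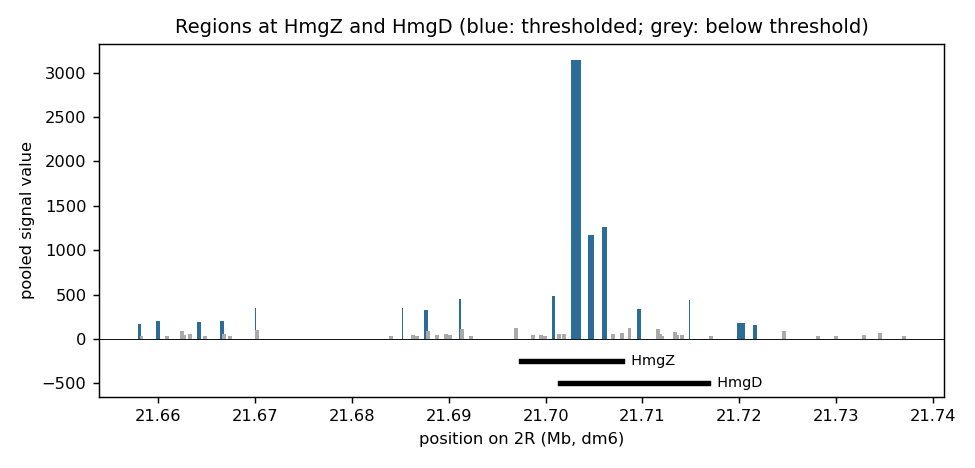
Pooled signal value of each region around HmgZ and HmgD on 2R (position in Mb, dm6), in blue for thresholded peaks and grey for regions below the threshold, with the spans of both genes as black bars. The tallest region, 1036 bp wide, lies where the genes overlap.

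Of 13945 protein-coding genes, 4574 (32.8%) had a summit within 250 bp of a TSS and are called bound here. A peak can count for more than 1 gene. The peak at Prosbeta1, in the proteasome list, lay nearest a TSS of Rrp42, while that at Rpn13 lay nearest its own. The list tests were not adjusted for such shared peaks. Lists of genes were compared with other genes by two-sided Fisher's exact tests adjusted over 30 lists, of which 10 were bound more often and 12 less often. Histone and rRNA genes are among the 12, though none had a unique TSS window. Among genes with unique TSS windows, 10 lists were bound more often and 9 less often. Ribosomal protein genes were bound in 73 of 93 cases (78.5%, log2 odds ratio 2.90 ± 0.36 SE, Fisher's exact adjusted p = 8.81e-19), with the strongest peaks at RpS27 (14.7 ± 3.43 times the median, n = 2), RpL7 (13.5 ± 2.56) and RpL23A (12.8 ± 1.03). Translation factor genes were bound in 34 of 54 cases (Fisher's exact adjusted p = 2.22e-05), among them eIF6 at 26.5 ± 9.30. Also bound more often were mitochondrial respiratory chain genes (44 of 86, Fisher's exact adjusted p = 0.00129), proteasome genes (26 of 48, adjusted p = 0.00631), cell cycle genes (19 of 28, adjusted p = 0.000501), spliceosome genes (17 of 26, adjusted p = 0.00276) and genes of the actin and tubulin cytoskeleton (8 of 11, adjusted p = 0.0139).

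Trithorax group genes, which maintain active gene states, were bound more often, in 14 of 15 cases (Fisher's exact adjusted p = 6.43e-06, the exception being ash1), with brm (3L 15982848 to 15983170), the ATPase of a remodelling complex, at 16.8 ± 8.06. Polycomb group genes, which maintain silent states, were bound more often too, in 11 of 16 cases (Fisher's exact adjusted p = 0.0104), with E(z) at 7.21 ± 2.74. Genes for insulator and architectural proteins were bound more often, in 10 of 16 cases (Fisher's exact adjusted p = 0.0237), with Chro (3L 22878710 to 22879105) at 29.4 ± 4.70 and Cp190 at 15.6 ± 4.66.

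Cuticle protein genes and chemoreceptor genes were among the lists bound less often. No peak was found at 120 cuticle protein genes (95% Wilson interval up to 3.10%, Fisher's exact adjusted p = 1.87e-20), and 1 of 230 chemoreceptor and odorant-binding protein genes was bound (Obp99b, adjusted p = 3.32e-37). Lists with the same call were neuronal function genes (1 of 18, Syx1A, Fisher's exact adjusted p = 0.0183), muscle structure genes (2 of 20, Tm1 and Zasp52, adjusted p = 0.0422), digestive proteases and amylases (1 of 24, Jon74E, adjusted p = 0.0037), antimicrobial peptides (0 of 14, adjusted p = 0.0138) and the Enhancer of split complex (0 of 11, adjusted p = 0.0293). The chorion, yolk and vitelline list had 1 bound member of 19 (Fisher's exact adjusted p = 0.0186). That member was Cp190, an insulator protein that the list's name pattern took in along with Cp110, and neither is a chorion gene. Without both, a change made after the values were seen, 0 of 17 were bound (Fisher's exact adjusted p = 0.00332).

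Among non-coding genes, 39 of 290 tRNA genes (Fisher's exact adjusted p = 3.46e-13) and 11 of 269 snoRNA genes (adjusted p = 1.12e-29) were bound, less often than protein-coding genes. Of 111 replication-dependent histone genes 0 were bound (Fisher's exact adjusted p = 5.57e-19), and of 99 rRNA genes 0 (Fisher's exact adjusted p = 8.63e-17). Near-identical copies limit these counts, since no histone or rRNA gene had a TSS window with 90% or more unique 32-mers. No call was made for Hox genes (2 of 8), segmentation genes (8 of 25), dorsoventral and mesoderm genes (4 of 16), neural development genes (4 of 20), testis-specific genes (3 of 21), heat shock proteins (9 of 25), HMG-box genes (6 of 19) or snRNA genes (6 of 32). Of the 22 called lists, 17 were called in each replicate's own strongest 6844 regions as well, histone and rRNA genes included. The exceptions, with Fisher's exact adjusted p-values, were the proteasome (adjusted p = 0.0940 in replicate 1), insulator proteins (0.0811 in replicate 3, 0.0847 in replicate 1), neuronal function (0.109 in replicate 1), muscle structure (0.123 in replicate 3, 0.0845 in replicate 1) and the Enhancer of split complex (0.243 in replicate 1), while testis-specific (0.0278) and snRNA genes (0.0199) passed, as bound less often, in replicate 3. With peaks matched in both replicates, a set chosen after the data were seen, 8 lists lost their call, at Fisher's exact adjusted p-values of 0.0559 to 0.232: proteasome, neuronal function, muscle structure, chorion, insulator, antimicrobial peptide, Enhancer of split, and actin and tubulin. Counting summits within 500 bp ended the calls for muscle structure (0.213) and the Enhancer of split complex (0.288), and within 1000 bp those for both (0.0934 and 0.602) and the proteasome (0.0552), while testis-specific genes passed (0.0219). Counting gene bodies ended those for neuronal function (0.105) and muscle structure (0.188). Digestive genes lost theirs among genes with unique TSS windows (0.0621), and digestive (0.0534) and chorion genes (0.0552) with the number of TSSs as a covariate. In the strongest 3422 peaks the lists of proteasome, insulator, spliceosome (0.425), actin and tubulin, neuronal function, muscle, chorion, antimicrobial peptide and Enhancer of split genes lost their calls. In the strongest 1711, all lists bound more often except ribosomal proteins and translation factors did so, Trithorax (0.204), Polycomb (0.515), cell cycle (0.831) and respiratory chain genes (0.225) included. Digestive genes also lost their call there (Fisher's exact adjusted p = 0.457), which left 6 lists bound less often.

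**Figure D4:**
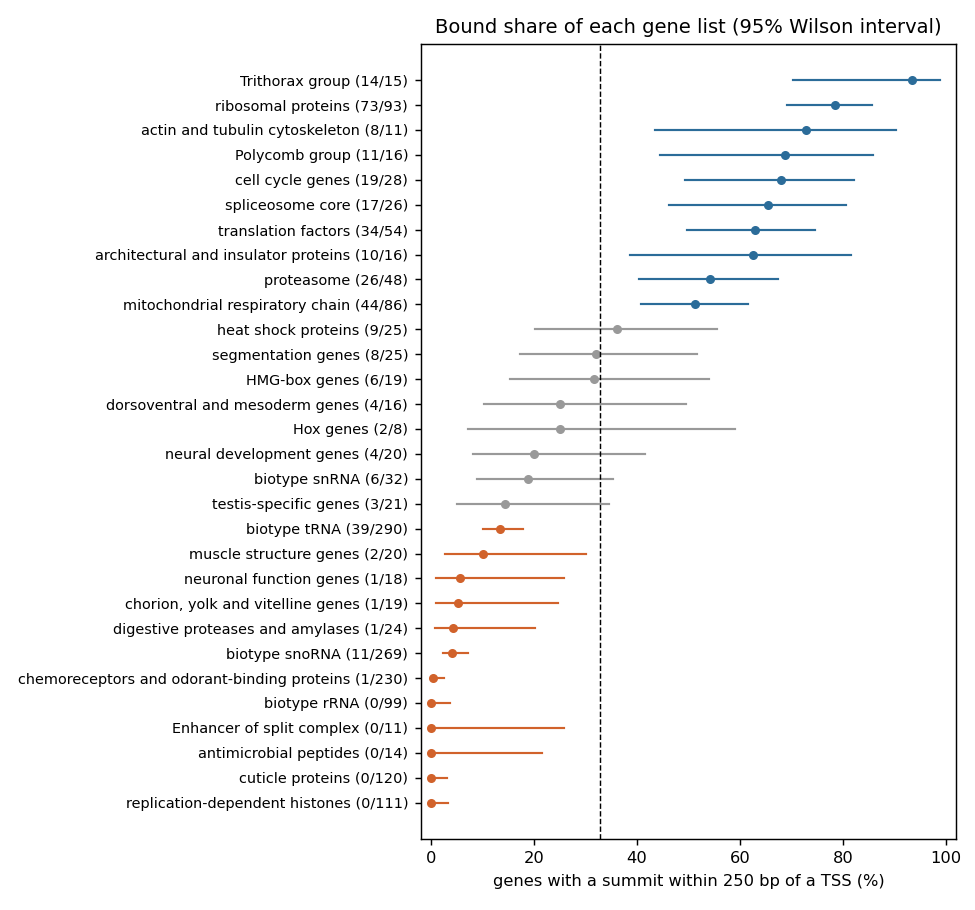
Percent of the genes of each list with a peak summit within 250 bp of a TSS, with 95% Wilson intervals; the dashed line marks the 32.8% of all protein-coding genes. Blue lists were bound more often, orange lists less often and grey lists passed no test, with bound and total members in brackets.

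Peaks were spread over all 6 arms analysed. The short chromosome 4 held 41 peaks, 30.8 per Mb (95% interval 22.7 to 41.7), 0.601 times the number set by its length (adjusted p = 0.00302, two-sided exact binomial test over 6 arms). Its genes were sparser (60.1 per Mb against 107 on 2L, 2R, 3L and 3R), and 27 of 80 were bound (33.8%), against 33.3% on those arms (odds ratio 1.02, 95% interval 0.640 to 1.62). The X held 47.8 per Mb, 0.934 times (adjusted p = 0.0248), and 2R held 54.4 per Mb, 1.06 times (exact binomial adjusted p = 0.0248). The densities on 2L (53.1), 3L (50.2) and 3R (51.5) did not pass the test. The binomial test treats peaks as independent, whereas peaks cluster along the arms, so its p-values are too small. In replicate 3 alone neither the X nor 2R passed (exact binomial adjusted p = 0.0664 for both). With exact binomial adjusted p-values, 2R also lost its call in the strongest 3422 peaks (0.0685), in matched peaks (0.0911) and in the strongest 1711, where its sign changed (0.853). The X lost its call in matched peaks (0.495), in the strongest 1711 (0.324) and on unmasked length (0.0790), and chromosome 4 lost its call in the strongest 1711 (log2 density -1.09). The 50 kb window with most peaks, 3R 11200001 to 11250000, held 18 against a mean of 2.56, 13 of them in promoters, near RpL3, RpS25, SdhC and Tctp among others. Windows at 3L 600001 to 650000 and at 3R 16200001 to 16250000, which covers peaks nearest tara, held 16 each.

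Of 24 sequence motifs compared with windows of matched G+C content, 11 were more frequent and 6 less frequent at an adjusted p under 0.05. These windows were not chosen to be promoters, whereas most peaks were. The motif bound by M1BP occurred in 4.85% of the windows of 100 bp to each side of the summits and in 0.137% of control windows (log2 odds ratio 5.20 ± 0.22 SE, Fisher's exact adjusted p = 3.46e-204). The DNA replication-related element occurred in 12.4% against 2.47% (2.48 ± 0.07), the BEAF-32 motif in 22.3% against 7.92% (1.74 ± 0.05) and the core promoter element known as Ohler motif 6 in 1.61% against 0.254% (2.68 ± 0.21). The consensus sequences of the DNA replication-related element (WATCGATW) and of BEAF-32 (CGATAS) overlap. A single site can count for both, so their frequencies are not independent. The core motif of the insulator protein CTCF occurred in 4.24% against 1.47% (1.57 ± 0.11) and that of Su(Hw) in 0.614% against 0.210% (1.56 ± 0.28). The Su(Hw) motif did not pass at promoter peaks alone (0.60, Fisher's exact adjusted p = 0.249). The less frequent ones included both HMG-box consensus sequences tested, for Sox proteins (10.4% against 12.6%, log2 odds ratio -0.32 ± 0.06) and for TCF (6.79% against 8.48%, -0.35 ± 0.07). Neither passed at peaks outside promoters (-0.07 and -0.19), TCF did not pass against flanking windows (-0.07), and Sox did not in the strongest 1711 peaks (-0.23, Fisher's exact adjusted p = 0.0920). No consensus for HmgZ itself was among the 24 motifs tested. The motif of Zelda, an activator of the early embryonic genome, did not pass the test (4.35% against 4.45%, Fisher's exact adjusted p = 0.780).

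Promoter peaks and other peaks carried different motifs, in a split chosen after the pooled result was seen. The DNA replication-related element had a log2 odds ratio of 3.20 at the 4004 promoter peaks and -0.23 at the 2840 others, a difference of 3.43 ± 0.21 SE (n = 6844 peaks, adjusted p = 5.19e-59). At peaks outside promoters neither the M1BP motif (0.84, Fisher's exact adjusted p = 0.263) nor Ohler motif 6 (0.09, adjusted p = 1) passed. The CTCF motif had 0.85 and 2.08 (difference -1.23 ± 0.22, n = 6844, adjusted p = 4.07e-08), and the GATA motif 0.03 and 0.64 (difference -0.61 ± 0.08, adjusted p = 2.45e-13). At promoter peaks the log2 odds ratio against the G+C-matched windows was 6.00 for M1BP and 3.39 for Ohler motif 6. Against 3343 promoter windows without a peak, drawn to match in G+C content, it was 1.89 ± 0.19 SE for M1BP (8.07% against 2.30%) and 1.45 ± 0.30 for Ohler motif 6. The DNA replication-related element had 1.44 ± 0.11, the BEAF-32 motif 1.48 ± 0.09 (30.9% against 13.8%) and the CTCF motif 0.93 ± 0.24, and the Su(Hw) motif did not pass (0.59, Fisher's exact adjusted p = 0.477). Those windows were all centred at -49 bp from a TSS, the median for promoter peaks, whereas the peaks' own distances vary, so motifs with a set place at the TSS cannot be compared in this way. Peaks are not replicates, so these tests describe this peak set and not the variation between embryo collections.

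The DNA under the summits was richer in A and T than the DNA 1000 bp away. At promoter peaks the 100 bp to each side of the summit were 59.8% A+T, 5.09 percentage points ± 0.178 (SE over 4004 peaks) above windows 1000 bp away. At other peaks they were 61.2% A+T, 2.59 points ± 0.184 (2840 peaks) above, though only 0.801 points above when 250 bp to each side were taken. Both differences had p = 1e-05 in paired sign-flip permutation tests, the smallest that 100000 resamples can give. The 6 arms as a whole were 57.8% A+T, above the windows 1000 bp from promoter peaks (54.8%) and below those from other peaks (58.6%). The difference at promoter peaks thus partly reflects flanks low in A+T. Base composition was not compared with promoters without a peak. The pooled signal of promoter peaks had a median of 200.4 against 181.9 for the others (difference 18.6, permutation p = 1e-05, the smallest possible).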

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

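The values here were chosen after the main results were seen. The 23156 pooled regions below the IDR threshold were not tested as peaks in the report, which uses them as a background, by rank and around HmgZ. Of them, 5446 (23.5%) had a summit within 250 bp of a TSS, above the 7.44% of random positions. A region of both replicates lay within 100 bp of 9067 of them (39.2%), for which no random level was computed. Some regions below the threshold overlap a thresholded peak, as several do around HmgZ, and were not left out. Both shares therefore include regions that are not separate from the peaks.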

How the results depend on the processing

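Alternatives named as added in the processing were chosen after the data were seen, and the other tests here were planned. Of 912 recomputed values, 745 kept their direction and side of the threshold, or moved within the spread or 1.5 times for counts. Of the others, 80 lost the threshold, 23 passed it, 8 moved further and 56 changed sign. Some of the 745 could not change, so their number overstates stability. Leaving out Cp110 and Cp190 altered the odds ratio of the chorion list only, yet all lists were counted again. Peaks where HmgZ and HmgD overlap were counted under both names. The feature classes promoter, coding exon, intron and intergenic, the TSS position, base composition and signal by class kept direction and call under each alternative run, though not always their size. Taking as many top pooled regions gave the same peaks as the thresholded set, so that setting tests nothing. Matching by reciprocal overlap of 50% gave a concordance of 63.8%. Log2 densities against length were, for 2R, 0.10 in the strongest 3422 peaks, -0.016 in the strongest 1711 and 0.091 in peaks matched in both replicates. They were, for X, -0.11 in the strongest 1711, -0.038 in matched peaks and -0.081 on unmasked length, and for chromosome 4 -1.09 in the strongest 1711, none of them past the threshold. In single replicates they ran from 0.075 to 0.13 for 2R and from -0.14 to -0.084 for X. Lists bound more and less often numbered 6 and 7 in the strongest 3422 peaks and 2 and 6 in the strongest 1711, where fewer peaks were tested. Those bound less often numbered 7 with matched peaks. They numbered 5 with the number of TSSs as a covariate, where 5 lists with no bound member could not be fitted and the chorion (-3.10) and digestive lists (-3.12) no longer passed. Motif log2 odds ratios changed sign against flanking windows for CACGTG (-0.046), poly(A) (0.22), homeobox (0.30), GC box (-0.67), TA repeat (0.24) and AP-1 (-0.048). Poly(A), called less frequent in the main test, passed there as more frequent (Fisher's exact adjusted p = 0.00262). Homeobox (7.72e-06) and GC box (1.57e-13), with no call in the main test, also passed there. Promoters without a peak were taken in windows all centred at -49 bp from a TSS, which bears on motifs with a set place there. Against these, log2 odds ratios changed sign for GAGA (-0.12), TATA box (-0.82), Initiator (-1.06), Pho (0.057), GATA (-0.19) and homeobox (0.19). GATA, called more frequent in the main test, passed there as less frequent (Fisher's exact adjusted p = 0.0162). TATA box (2.86e-16) and Initiator (8.46e-42), with no call in the main test, also passed as less frequent. At other peaks log2 odds ratios changed sign for the DNA replication-related element (-0.23), CACATG (0.31), Zelda (0.097), TATA box (-0.048) and Initiator (-0.054). Of these, CACATG passed as more frequent (Fisher's exact adjusted p = 0.0108), and in all 2 motifs were less frequent there. At promoter peaks log2 odds ratios changed sign for GC box (-0.15). In the strongest 1711 peaks they did for GATA (-0.030), Initiator (-0.20) and GC box (-0.12), and within 50 bp for Zelda (0.12), CACATG (0.039) and GC box (-0.12). Initiator also did in the strongest 3422 peaks (-0.061), in matched peaks (-0.0036) and between single replicates (-0.065 to 0.11), and GC box between single replicates (-0.0034 to 0.036). Further sign changes were in results that passed on neither side. For non-coding exons, log2 folds were -0.29 in the strongest 3422 and -0.29 in the strongest 1711 peaks, -0.13 to 0.052 in single replicates, -0.10 in matched peaks, -0.14 and -0.034 with promoters drawn to 500 and 1000 bp, -0.40 against the weakest pooled regions and -0.0046 on unique 32-mers. For 3R, log2 densities were -0.031 to 0.010 in single replicates, -0.022 in matched peaks and -0.0036 on unmasked length. For HMG-box genes, log2 odds ratios were 0.31 in the strongest 1711 peaks, 0.87 and 0.71 in replicates 3 and 1, 0.17 in matched peaks, 0.33 and 0.68 within 500 and 1000 bp, 0.31 with gene bodies and 0.14 with unique windows. For dorsoventral genes they were -0.46 to 0.45 in single replicates, 0.42 and 0.19 within 500 and 1000 bp and 1.44 with gene bodies. Hox genes had 2.13 with gene bodies, snRNA genes 0.042 in the strongest 1711 peaks, segmentation genes 0.20 within 500 bp and heat shock proteins -0.032 within 1000 bp. Where no cause is given, the cause was not tested. With no read counts, the effect of depth could not be measured.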

Other observations

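Bound genes were often members of divergent pairs, that is, genes on opposite strands with TSSs within 500 bp of each other, a comparison chosen after the main results were seen. Of 4574 bound protein-coding genes, 2285 were in such pairs, against 1530 of 9371 unbound genes, an odds ratio of 5.12. Genes in such pairs were bound in 59.9% of cases and other genes in 22.6%. A single peak near 2 such TSSs can mark both genes, so the genes of a pair are not independent. Genes in pairs also had more chances to be called bound. The definitions alone therefore raise the odds ratio and the difference in shares, by an amount that was not measured. The tests of gene lists were not adjusted for membership in such pairs. Bound genes had a median length of 2954.5 bp and unbound genes 1863 bp. Annotated transposable elements held 6 of 6844 summits (0.0877%). They held 1.46% ± 0.139 (SD) of positions placed only where a 32-mer is unique (two-sided placement p = 0.002, n = 6844, the smallest possible). Those positions were not matched for distance to a TSS, whereas most summits lay at promoters. Part of the difference may therefore restate the high promoter share.

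Of the tests that follow, both on the HmgZ locus were chosen after its regions and their signal had been seen; the others were written before their values were seen. No biological explanation was tested, since the design has 1 group. The HmgZ locus held 3 of the 100 strongest peaks. For signal from 1 replicate alone, the test took the 2 of these that had not been picked for their percentile. They were at percentile 99.7 or higher in each replicate, above the bound of 99 set for this test. These 2 peaks were thus strong in both replicates. That outcome was likely beforehand, since they were ranked by pooled signal, which comes from both replicates. The brm peak, at pooled rank 78, also passed the bound (percentiles 99.5 and 99.8). No conclusion on the locus as a whole is drawn from this test. Extra copies of the tagged fragment in this line might raise the signal over the whole locus. The window of 39.24 kb around HmgZ and HmgD held 23 regions below the threshold, the 83.7th percentile among 249 windows with a like number of peaks, between the bounds of 75 and 95 set for this test, so that this explanation stays open.

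Reads that cannot be placed uniquely may account for the lack of peaks at histone and rRNA genes, where the median share of unique 32-mers near TSSs was 0%. At cuticle and chemoreceptor genes that share was 100%, which argues against the same explanation there. What sets these genes apart was not tested further.

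The lower peak density on the X may have technical sources, and it lost its call under several alternatives. Genes were sparser there (93.5 per Mb against 107 on 2L, 2R, 3L and 3R). Genes on the X were also bound less often, 29.9% against 33.3% (odds ratio 0.854, 95% interval 0.773 to 0.943). That interval below 1 was the outcome set to go against sparser genes as the whole cause. Peak density on the X was 0.917 times that on those arms, a smaller drop than that in genes per Mb. This test therefore cannot exclude sparser genes as a cause of the lower peak density. A lower copy number of the X in embryos of both sexes could reduce signal there. The median signal of promoter peaks on the X was 0.937 times that on those arms (95% bootstrap interval 0.893 to 0.979), an interval that includes the bound of 0.9, so this stays open.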
